A study of Mus musculus with 4 samples.

How the data were processed

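CTCF, a zinc-finger protein that binds insulators and the anchors of chromatin loops, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in CD4 T cells of the mouse thymus. Per the labels' protocols, the cells were fixed with formaldehyde and the libraries were read on an Illumina HiSeq2500. The series held 4 libraries: 1 CTCF ChIP and 1 input of conventional CD4 T cells negative for a Foxp3 reporter (Tcon), and 1 CTCF ChIP and 1 input of regulatory T cells (Treg). The cell type label of the Treg ChIP library names a DSM mutant, whereas the label of its input names wild-type cells. Both libraries carry Treg in their titles, so Treg stands below for the library labelled Treg, and the genotype of those cells was not settled.

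The submitters' processing notes name BWA, MACS2 and the mm9 genome, and versions and settings are not given in the sources used here. The labels tie 1 deposited peak list to the ChIP and input libraries of each cell type, so the lists were taken as 1 per cell type. The lists have no header line, and their columns follow the order of the narrowPeak format. The ratio in each deposited list is the fold enrichment of a peak over its background, as the authors' peak caller gave it. The deposited −log10 values are those of the p and q of each peak, as the authors' caller gave them. The smallest −log10 q was 1.35 in the Tcon list and 1.34 in the Treg list, so every listed q lay below 0.05. Fold enrichment and −log10 q were used only to describe, rank or filter peaks within a list. Read depth is unknown for all 4 libraries, and a difference in depth between them changes how many weak sites pass a caller's threshold.

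Coordinates are on mm9 and count from 1. The annotation was GENCODE M1, of Ensembl release 65, on the same assembly. Peaks on contigs not placed on a chromosome were left out of the comparisons. Peaks of the lists were compared with bedtools 2.31.1, and a peak that overlapped a peak of the other list by at least 1 bp was called shared. A peak without such an overlap was called Tcon-only or Treg-only, which states that the other list has no peak there and does not state that CTCF was absent. Overlap by chance was taken from 100 random circular shifts of the other list within each chromosome. Summits within 1 kb of a transcription start of any gene were called promoter summits. The CTCF core motif CCASYAGRKGGCRS, of 14 bases, was searched on both strands within 50 bp of each summit with at most 2 mismatches, and again 1 kb to each side as background. Peaks were counted at a gene when the summit lay in the gene or within 10 kb of it.

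For 6 fixed gene lists, the number of Tcon-only and of Treg-only peaks was given as a percentile among 10000 random gene lists of the same size matched on their number of peaks. The peaks of a list were summed over its genes, so a peak near several of them was counted at each. Random lists were not matched on such neighbours, and the intervals of these shares take no account of them. A percentile of at least 97.5 or at most 2.5 was taken as standing apart. The lists were Treg signature, Tcon or Foxp3-repressed, T cell lineage, CTCF, cohesin and textbook CTCF loci, other cell types, and housekeeping genes. Kcnq1ot1, Pcdha1, Pcdhga1, Firre, Adgre1, Tcrg-C1 and Hprt1 had no entry of that name in the annotation. Windows of 1 Mb with at least 10 peaks were searched for a high share of list-only peaks. Antigen receptor loci were defined after the lists had been examined. Annotated gene segments at most 1 Mb apart were joined, and each joined group of at least 5 segments was taken from its first to its last segment. The joining distance was shortened to 1 Mb after a longer one had drawn a far segment into the T cell receptor beta locus.

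Named peaks were, per list, the 10 list-only peaks of highest fold enrichment with −log10 q of at least 5 and at least 1 kb from the other list, and the 5 strongest shared peaks. Named genes were the 12 genes with the strongest such peak per class, up to 25 of the 37 fixed-list genes with such a peak, and Foxp3, Il2ra, Ctla4, Ikzf2, Cd4, Cd3e, Satb1, Bach2, Tcf7, Myc, H19 and Ctcf. Not all of these are described. The 5 windows with the highest share of each class were taken as well. The groups, the gene lists, the naming rule and the alternatives, except those named as later, were fixed before the data were examined.

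With 1 ChIP library per cell type there was no replicate check, no test between cell types and no p-value. Shares have exact Clopper-Pearson 95% intervals, and differences between shares have 95% intervals by normal approximation. Both treat peaks as the units and cover counting error only. The alternatives were other overlap rules, stricter −log10 q, lists of equal number, merged intervals, autosomes only, other strength measures, other promoter and gene distances, other motif settings and other window sizes. At a stricter −log10 q both lists were filtered unless stated, and peaks were classed anew. A peak could then be list-only because the overlapping peak of the other list had been filtered out. The overlap, motif and gene list steps were tested on simulated data. The motif search found 100% of 2000 planted sites, an outcome fixed by planting them with at most the 2 mismatches allowed. It called 1.95% of 2000 random sequences. Of 100 simulated gene lists without an effect, 3% reached the percentile of 97.5. Peaks were simulated independently per gene, without neighbours that share peaks, so this does not check the threshold for the real lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.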

Results

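CTCF occupancy was measured in 2 kinds of thymic CD4 T cells, Tcon and Treg, with 1 ChIP library and 1 input library each. The Tcon list held 28301 peaks and the Treg list 28616, of which 28240 and 28556 lay on assembled chromosomes. Median peak width was 281 bp in the Tcon list and 248 bp in the Treg list. Median fold enrichment, as the authors' caller gave it, was 14.6 in the Tcon list and 11.6 in the Treg list. These scores were not compared across lists. Tcon peaks covered 0.308% of the genome and Treg peaks 0.275%. Chromosome X carried 693 Tcon and 699 Treg peaks.

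The first comparison asked which CTCF sites of one cell type were also listed in the other. The strongest peaks of both lists were shared. In the Tcon list the highest fold enrichment, 106, was in a coding exon of Gdf15, a stress-induced cytokine gene, at chromosome 8: 73153551–73154445. The overlapping Treg peak had a fold enrichment of 88.6. In the Treg list the strongest peak, at 99.7, lay in an intron of Ctif at chromosome 18: 75759245–75760014. The promoter of Sh3glb1 on chromosome 3 held the third strongest Tcon peak and the second strongest Treg peak. Further shared peaks of this kind lay near Uvrag, an autophagy gene, in an intron of Iffo2, and at the promoter of Acbd4.

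Of the 28240 Tcon peaks, 24765 were shared, which is 87.7% (95% interval 87.3 to 88.1). Of the 28556 Treg peaks, 24811 were shared, which is 86.9% (86.5 to 87.3). Shifted lists gave means of 0.619% and 0.610%. Summits of shared peaks lay a median of 15 bp apart, and 94.1% lay within 50 bp. The remainder were 3475 Tcon-only and 3745 Treg-only peaks. Of these, 356 Tcon-only and 264 Treg-only peaks lay within 1 kb of a peak of the other list. With both lists at −log10 q of at least 10 there were 2961 Tcon-only and 2164 Treg-only peaks, the opposite order.

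Shared peaks became more frequent with peak strength. In the lowest decile of fold enrichment, 50.8% (49.0 to 52.7) of Tcon peaks and 50.4% of Treg peaks were shared. In the highest decile, 100% were shared in both lists. The 3 lowest deciles held 87.5% (86.4 to 88.6) of the Tcon-only peaks and 86.2% (85.0 to 87.3) of the Treg-only peaks. In the upper 5 deciles, 43 of 14120 Tcon peaks and 57 of 14278 Treg peaks were list-only.

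**Figure D1:**
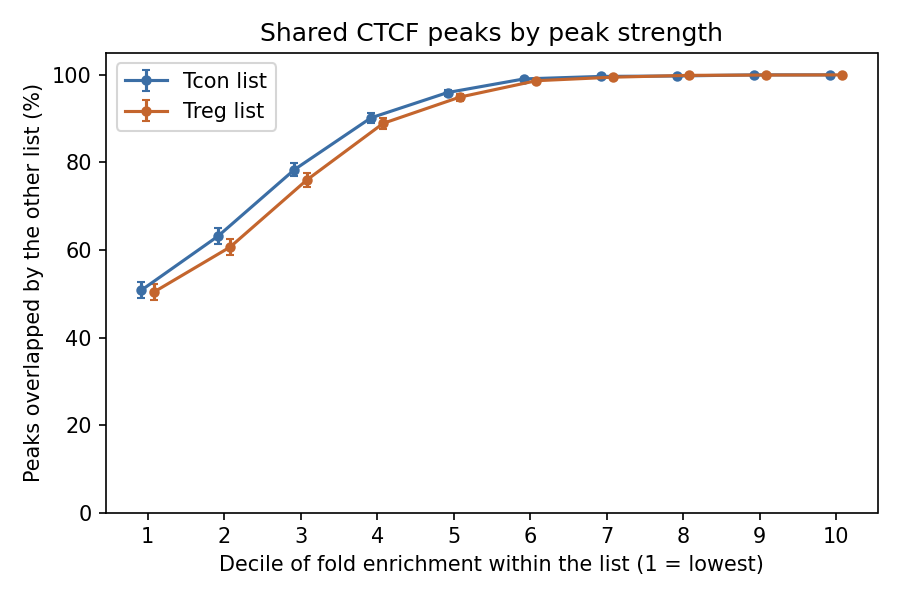
Percent of peaks overlapped by the other list (vertical axis) in each decile of fold enrichment within the list (horizontal axis), for the Tcon and the Treg list, with exact 95% intervals as bars. Both lists rise from 50.8% and 50.4% in the lowest decile to 100% in the highest.

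Strong list-only peaks were few, and of the 10 strongest of each list 6 Tcon-only and 3 Treg-only peaks were intergenic. The strongest Tcon-only peak, with a fold enrichment of 24.6, was intergenic at chromosome 7: 128163816–128164144, near Gm9234 and 4933427G17Rik. Tshr, the thyrotropin receptor gene, held a Tcon-only intron peak of fold enrichment 23.9 at chromosome 12: 92762104–92762377, without the CTCF motif, besides 3 shared peaks. The promoter of Gart, a purine synthesis enzyme gene, held one of 21.8 at chromosome 16: 91646195–91646458, which also lies within 10 kb of Son. Ldlrad3 held 3 Tcon-only peaks, of which an intron peak at chromosome 2: 101870873–101871164 had a fold enrichment of 21.5. Ubqln2 and Rbfox2 each had 1 Tcon-only peak in the flanking sequence, at 22.4 and 22.5. Tgfbr3, which encodes a TGF-beta co-receptor, had a promoter peak of 20.7 at chromosome 5: 107718279–107718566, also without the motif.

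The strongest Treg-only peak, with a fold enrichment of 23.2, was intergenic at chromosome 10: 51125032–51125283. Next came the promoter of Cebpa, a myeloid transcription factor gene, at chromosome 7: 35904146–35904366 with 18.6. Neither list had any other peak within 10 kb of Cebpa. Gas7 held an intron peak of 16.6 and Cables1 had one of 15.6 in the flanking gene Gm6277. Promoters of Nkd2, an inhibitor of Wnt signalling, and of Ptchd2 each had a Treg-only peak of 16.1, that of Nkd2 without the motif. Il27ra, the interleukin 27 receptor gene, had one of 15.1 at its promoter, at chromosome 8: 86565989–86566249, without the motif. A peak of 17.1 lay in introns of Gm10406 and Gm3739 on chromosome 14, overlapping gene models of a multi-copy family, where placement of reads is uncertain.

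The CTCF core motif was found within 50 bp of 82.0% (81.6 to 82.5) of shared Tcon summits. It was found at 53.4% (51.7 to 55.1) of Tcon-only summits and at 67.5% (66.0 to 69.0) of Treg-only summits. Windows 1 kb away held it in 2.998%, 2.66% and 2.98% of cases. Promoter summits made up 15.7% (15.2 to 16.1) of shared, 20.7% (19.4 to 22.1) of Tcon-only and 14.5% (13.4 to 15.7) of Treg-only peaks. Intergenic summits made up 42.6%, 34.8% and 43.6%. At promoters, 32.5% of Tcon-only and 43.6% of Treg-only summits had the motif. Elsewhere the shares were 58.9% and 71.6%.

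**Figure D2:**
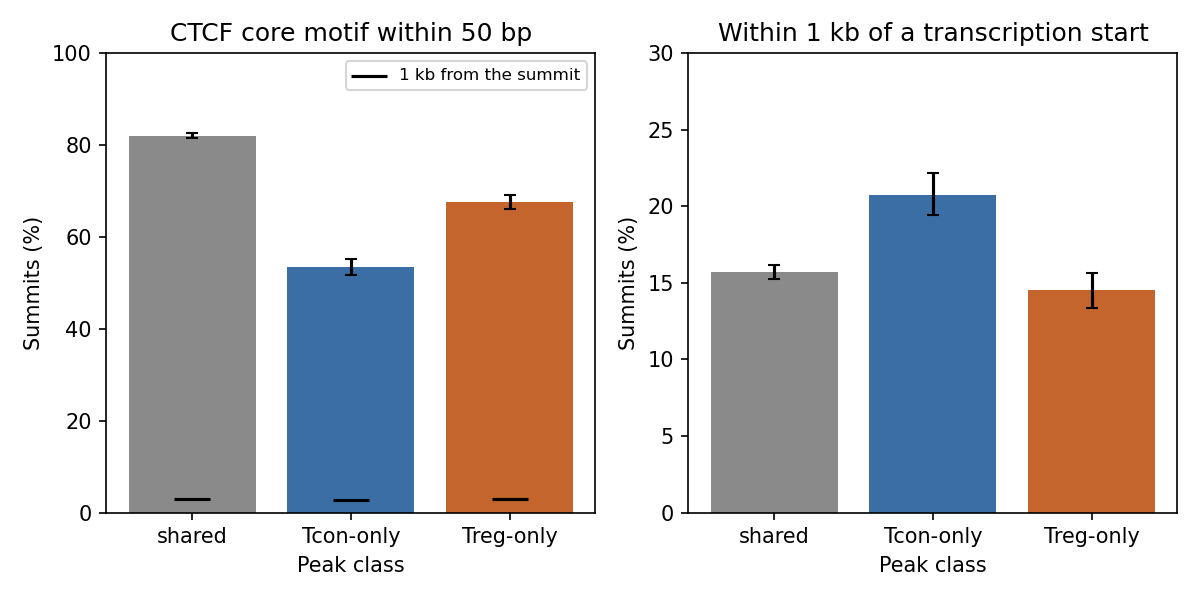
Percent of summits with the CTCF core motif within 50 bp (left) and within 1 kb of a transcription start (right) for shared, Tcon-only and Treg-only peaks, with exact 95% intervals; black dashes mark the motif share 1 kb from the summit. Motif shares were 82.0%, 53.4% and 67.5%, and promoter shares 15.7%, 20.7% and 14.5%. The classes were not matched on peak strength.

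The second comparison asked whether genes that set Treg cells apart carry peaks of one list. The 40 Treg signature genes had 82 peaks, of which 62 were shared, 16 Treg-only and 4 Tcon-only. Treg-only peaks lay at 11 genes: Rora had 4, Tnfrsf9 and Nrp1 had 2 each, and Ctla4, Ikzf2, Tnfrsf18, Capg, Klrg1, Entpd1, Penk and Lgals1 had 1 each. Matched random lists had a median of 9 Treg-only peaks, and the Treg signature stood at percentile 98.85 of them. It stood at percentile 3.78 for Tcon-only peaks, and between 0.135 and 2.12 with the gene body alone, with 50 kb to each side, at −log10 q of at least 5 and with only peaks without the motif. With only motif-bearing peaks it stood at percentile 31.2, with 3 Tcon-only peaks against a random median of 4. The Treg-only percentile was below the threshold for the gene body alone (94.3), with both lists at −log10 q of at least 5 (87.1), with only motif-bearing peaks (82.9), and without Rora (95.8), Tnfrsf9 (97.1) or Nrp1 (97.1). It was above the threshold with 50 kb to each side (99.8), with only peaks without the motif (99.7) and without any other single gene of the 11. Tnfrsf9, Nrp1, Entpd1 and Lgals1 are named with the others because they are part of the count of Treg-only peaks. With 50 kb to each side, Ctla4 and Icos both counted the Treg-only peak at chromosome 1: 60996967–60997140.

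Rora, a nuclear receptor gene at chromosome 9: 68501593–69236053, had 10 shared and 4 Treg-only peaks. The strongest of the latter was an intron peak of fold enrichment 10.1, and the others had 8.56, 5.04 and 4.49. Ctla4, an inhibitory receptor of Treg cells, had a Treg-only promoter peak of 4.05 without the motif and no shared peak. Ikzf2, which encodes Helios, had 1 shared peak and 1 Treg-only peak of 4.39, also without the motif. The Treg-only peaks of Ctla4 and Ikzf2 had −log10 q of 2.82 and 3.13, and both lay in the lowest decile of the Treg list. Tnfrsf18, the gene of the receptor GITR, had a Treg-only peak of 7.79 beyond the end of the gene, within 1 kb of another transcription start. Klrg1 and Penk had Treg-only peaks of 7.55 and 9.07. Il2ra, the interleukin 2 receptor alpha gene, had 3 shared peaks and no other. Foxp3, the lineage factor of Treg cells at chromosome X: 7156802–7172369, had no peak within 10 kb in either list. The nearest Treg peak to its left, at 38.1 kb, was Treg-only with a fold enrichment of 6.04, and the nearest shared peak to its right lay 50.3 kb away.

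**Figure D3:**
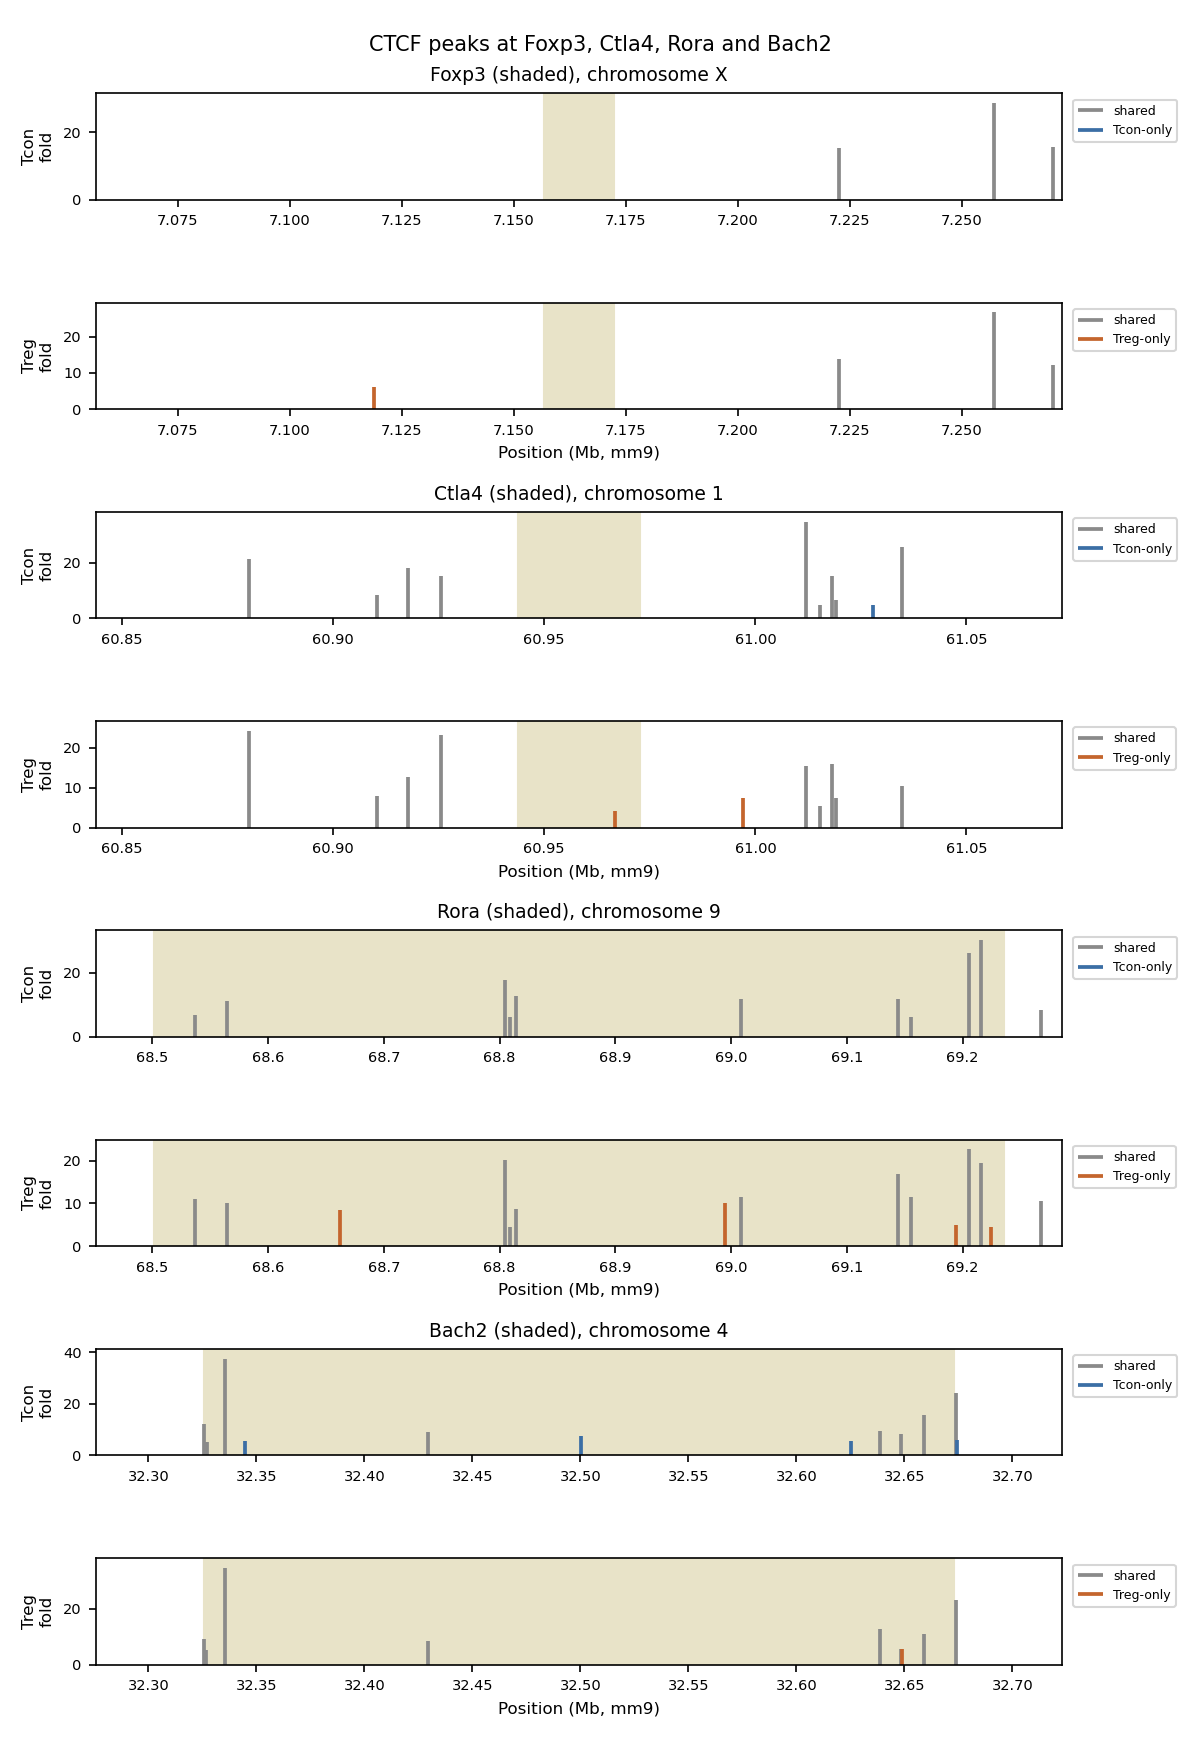
CTCF peaks around Foxp3 and Ctla4 (100 kb to each side) and Rora and Bach2 (50 kb to each side), drawn by summit position on mm9 (horizontal axis, Mb) and fold enrichment within each list (vertical axis), with the gene shaded, shared peaks grey and list-only peaks coloured. Rora with 10 kb to each side has 10 shared and 4 Treg-only peaks, Bach2 has 4 Tcon-only peaks, and Foxp3 itself has none.

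Genes of conventional T cells or repressed by Foxp3 had 87 peaks, of which 14 were Tcon-only (percentile 85.0, and 99.2 with 50 kb to each side) and 7 Treg-only (23.4). Bach2, a repressor that keeps T cells from differentiating, had 8 shared, 4 Tcon-only and 1 Treg-only peak. Ccr7, a homing receptor gene, and Actn1 had 2 Tcon-only peaks each, and Tgfbr3 also had 2. Lef1 had 5 shared peaks and 1 of each other class. Tcf7 and Satb1, both transcription factors of T cells, had 2 and 1 shared peaks and no list-only peak.

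T cell lineage genes had 82 peaks, of which 15 were Tcon-only (percentile 96.0) and 8 Treg-only (42.4). Cd4, the co-receptor gene, had 2 shared peaks and a Tcon-only intron peak of 7.28. Cd3e, a T cell receptor subunit gene, had 2 shared peaks and a Tcon-only peak of 7.84 in its UTR. Bcl11b had 5 shared, 2 Tcon-only and 1 Treg-only peak, and Cd28 had 1 Tcon-only peak of 9.21 without the motif. Ikzf3 had 3 Treg-only and 1 Tcon-only peak. The percentile for Tcon-only peaks was 99.035 for the gene body alone, 99.3 with both lists at −log10 q of at least 5 and 69.9 with 50 kb to each side. In the filtered lists 17 of 73 peaks were Tcon-only, a class that there includes peaks whose overlapping Treg peak was filtered out.

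The list of CTCF, cohesin and textbook CTCF loci had 49 peaks, with 5 of each list-only class (percentiles 47.3 and 50.3). H19, an imprinted gene, had 1 shared and 1 Tcon-only peak of fold enrichment 11.5 without the motif. That Tcon-only peak lay within 1 kb of a Treg peak. Ctcf itself had 2 shared peaks and 1 Treg-only promoter peak of 6.55 without the motif, and Smc3, a cohesin gene, had 3 shared and 1 Treg-only peak. Myc had 2 shared peaks. Within 1 kb of a transcription start it also had a Tcon-only peak at chromosome 15: 61818393–61818535 and a Treg-only peak at 61818612–61818822. These neighbours count as list-only because they do not overlap. The Tcon-only peak had a fold enrichment of 4.30 and no motif, and the Treg-only peak had 13.1 and the motif. Genes of other cell types had 27 peaks, 2 Tcon-only (33.3) and 1 Treg-only at Pax5 (11.96). Housekeeping genes had 35 peaks, 2 Tcon-only (17.4) and 7 Treg-only (94.3), among them 2 at Rpl13a and 2 at Polr2a. Of the 12 percentiles, 1 passed the threshold, where 0.60 would by chance.

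**Figure D4:**
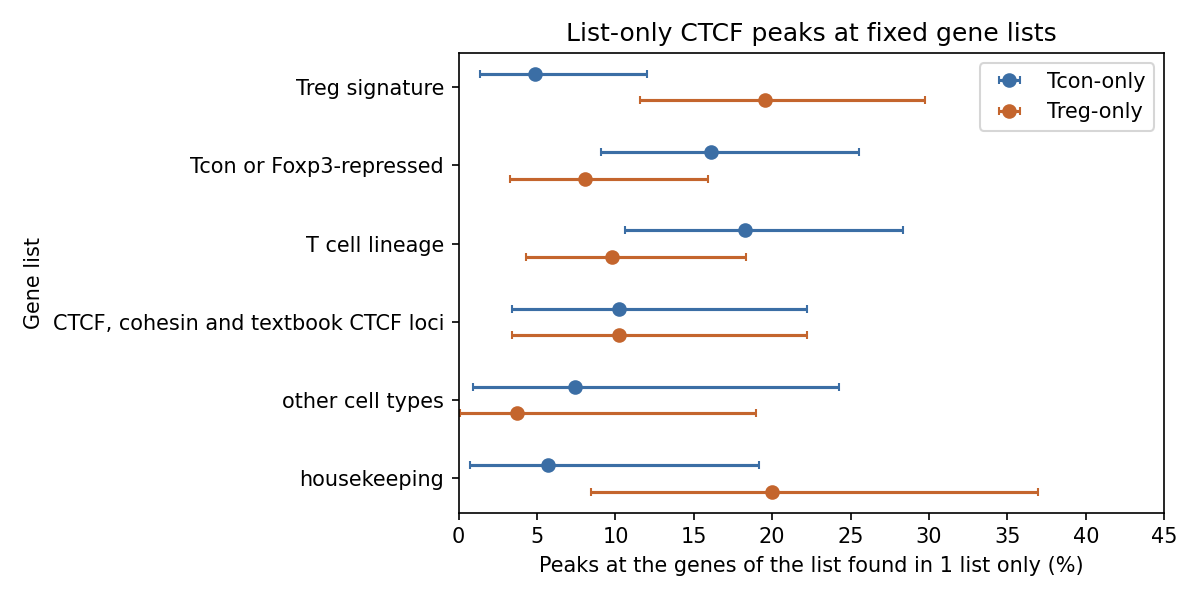
Percent of the peaks at each fixed gene list that were Tcon-only or Treg-only (horizontal axis), with exact 95% intervals that cover counting error only. At the Treg signature 19.5% of peaks were Treg-only and 4.88% Tcon-only, and at housekeeping genes 20% and 5.71%. A peak near several genes of a list counts at each.

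The third comparison asked whether list-only peaks gathered in some regions. Among 1243 windows of 1 Mb with at least 10 peaks, 4 had at least 50% Tcon-only and 3 at least 50% Treg-only peaks. The number of such windows expected by chance was not estimated. The windows below were picked for their high shares, and their intervals take no account of this. On chromosome 5 from 89 to 90 Mb, which holds Dck and Slc4a4, 8 of 13 peaks were Tcon-only, or 61.5% (31.6 to 86.1). The window with Tgfbr3 and Cdc7 on chromosome 5, from 107 to 108 Mb, had 8 of 16. The window with Cdyl on chromosome 13, from 35 to 36 Mb, had 6 of 11. On chromosome 5 from 8 to 9 Mb, with Abcb1a and Abcb1b, 6 of 10 peaks were Treg-only, or 60.0% (26.2 to 87.8). Chromosome 14 from 6 to 7 Mb, a stretch of repeated Gm gene models, also had 6 of 10, and the Krtap window on chromosome 16 from 89 to 90 Mb had 6 of 12. On chromosome 9 from 3 to 4 Mb, 39 of 64 peaks were Tcon-only. All 39 lay in the first 100 kb of sequence there, none had the motif, and the median fold enrichment of the window's peaks was 1.70.

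Receptor gene segments were looked at after the windows had been seen. The T cell receptor alpha and delta locus on chromosome 14 had 95 peaks, of which 80 were shared, 14 Tcon-only and 1 Treg-only. Over all 31985 peaks, 10.9% were Tcon-only and 11.7% Treg-only.

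**Figure D5:**
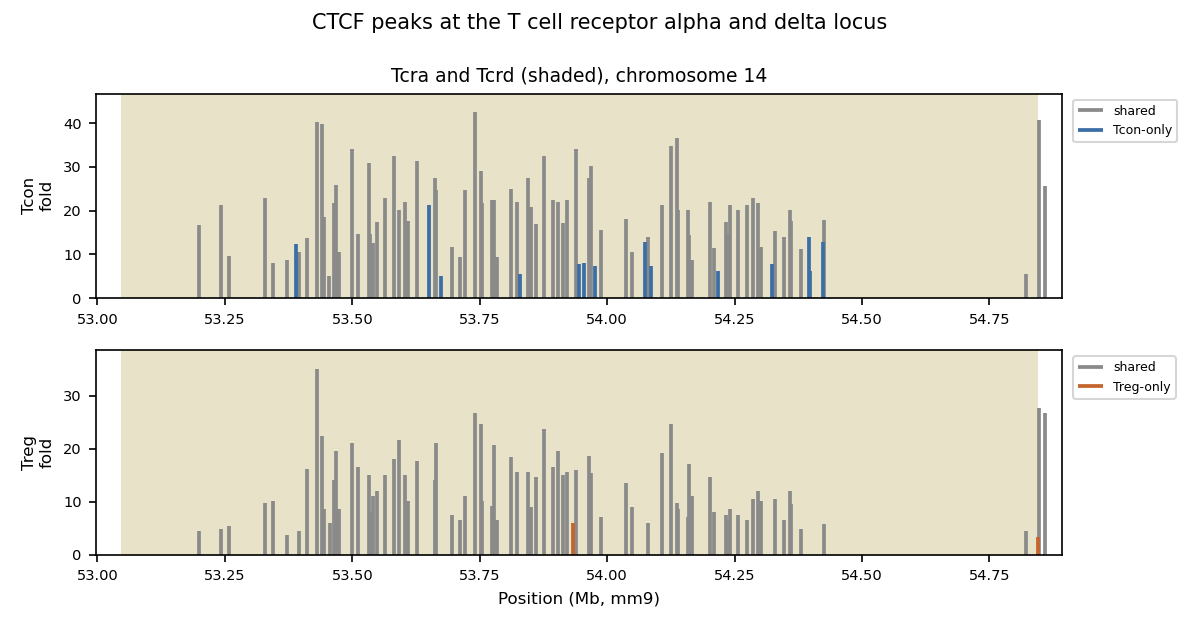
CTCF peaks at the T cell receptor alpha and delta locus (shaded) on chromosome 14 by summit position on mm9 (horizontal axis, Mb) and fold enrichment within each list (vertical axis), with 50 kb to each side. Shared peaks are grey, and the shaded span holds 14 Tcon-only and 1 Treg-only peak.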

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

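Peaks on contigs not placed on a chromosome stand outside the comparisons, and both lists held such peaks. The Tcon list had 61 and the Treg list 60, and 54 of each were shared. Their median fold enrichment was 12.3 in the Tcon list and 9.11 in the Treg list. No explanation was tested for them.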

How the results depend on the processing

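Across 202 comparisons of a result other than a named peak with an alternative, 149 stayed within the interval, within 1.5 times the count or on the same side of the threshold. Named peaks are left out of this count, since the naming rule largely fixes their outcome. The count still includes merged intervals, which could change nothing because neither list held overlapping intervals. Each overlap alternative enters it both as a number of list-only peaks and as a percent shared. The chromosome 9, motif-only, no-motif and left-out gene alternatives were chosen after seeing the data. Tcon and Treg peaks were shared at 85.7% and 84.8% with reciprocal overlap of 50%, 87.1% and 86.1% with summits within 100 bp, and 89.0% and 87.8% within 1 kb. They were shared at 87.0% and 88.0% with both lists at −log10 q of at least 5, and 86.6% and 89.9% at 10, where fewer peaks were kept. Treg-only peaks outnumbered Tcon-only peaks in the main comparison, but there were 3502 Tcon-only and 3200 Treg-only at 5, 2961 and 2164 at 10, 2783 and 2758 with only the counted list at 5, and 3610 and 3568 with lists of equal number. They were shared at 89.7% and 89.7% with only the counted list at 5, and 87.2% and 87.4% with lists of equal number. In the lowest decile 47.4% and 44.4% were shared with reciprocal overlap, and 48.2% and 46.8% with deciles of −log10 q; in the highest, 99.1% and 99.1% with reciprocal overlap. Promoter shares of shared, Tcon-only and Treg-only summits were 25.7%, 30.5% and 24.1% at 2.5 kb, and that of Treg-only summits was 12.9% at −log10 q of at least 5. Motif shares were 54.2%, 24.5% and 33.9% with at most 1 mismatch, and 85.7%, 62.7% and 75.7% within 100 bp. The Treg signature percentile for Treg-only peaks was 94.3 for gene bodies, 87.1 at −log10 q of at least 5, 82.9 with the motif, 95.8 without Rora and 97.1 without Tnfrsf9 or Nrp1; it was 99.8 with 50 kb and 99.7 without the motif. Its percentile for Tcon-only peaks was 2.12 for gene bodies, 0.135 with 50 kb, 0.545 at −log10 q of at least 5 and 1.36 without the motif, but 31.2 with the motif. T cell lineage genes stood at 99.035 for gene bodies and 99.3 at −log10 q of at least 5 for Tcon-only peaks but at 69.9 with 50 kb, and Tcon or Foxp3-repressed genes at 99.2 with 50 kb but at 86.9 and 86.3 for gene bodies and at −log10 q of at least 5. Of 7281 peaks without the motif, 22.2% were Tcon-only and 16.7% Treg-only. Among these, Treg-only peaks made up 37.5% (9 of 24) at the Treg signature, 42.9% (3 of 7) at housekeeping genes and 0% of 4 at genes of other cell types; Tcon-only peaks made up 23.5% (4 of 17) at CTCF loci and 25% (1 of 4) at genes of other cell types. Of these only the Treg signature passed the percentile threshold. Of 32 motif-bearing peaks at CTCF loci, 3.13% were Tcon-only. Windows with at least 50% Tcon-only and Treg-only peaks numbered 1 and 1 at 500 kb and 2 and 4 at 2 Mb, against 4 and 3 at 1 Mb. Where the construction of an alternative does not show it, the cause was not tested. No paired analysis was possible because each cell type has 1 ChIP library. Read depth is unknown, and it limits what the absence of a weak peak from a list shows.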

Other observations

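The tests on the motif share and that of weak peaks at the T cell receptor alpha and delta locus were chosen only after the results were seen, as were the loci themselves. The other tests in this part were written before their result was seen, but the readings that leave Treg identity, rearrangement and chance placement open were set afterwards.

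Antigen receptor loci rearrange to make receptor genes, and 4 of the 5 examined had more Tcon-only than Treg-only peaks. The T cell receptor alpha and delta locus, at chromosome 14: 53047603–54842772, had 80 shared, 14 Tcon-only and 1 Treg-only peak. Against shares of 10.9% Tcon-only and 11.7% Treg-only over all peaks, its Treg-only count was low and its Tcon-only count nearer the general share. Of its 14 Tcon-only peaks, 13 had the CTCF motif, and the strongest had a fold enrichment of 21.3. The T cell receptor beta locus on chromosome 6 had 13 shared, 5 Tcon-only and no Treg-only peaks. The immunoglobulin heavy chain locus on chromosome 12 had 63 shared, 15 Tcon-only and 3 Treg-only peaks, the T cell receptor gamma locus on chromosome 13 had 1, 2 and 0, and the kappa locus on chromosome 6 had 8, 2 and 2.

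The excess of Tcon-only over Treg-only peaks at the alpha and delta locus was 13. Of 2891 overlapping windows of the same length, outside the locus and with at least 48 peaks, 0.657% had as large an excess. Because the locus was picked after its peaks had been seen, this does not exclude chance placement of list-only peaks. A calling threshold stays open: 64.3% of the locus's Tcon-only peaks lay in the 3 lowest deciles of strength, as did all 5 at the beta locus and 12 of 15 at the heavy chain locus. Rearrangement of gene segments in T cells was taken beforehand to predict an excess at the beta locus, where it was 5. That prediction holds only if Tcon and Treg differ in rearrangement, which was not measured. The weak peaks at the beta locus fit a threshold too, and the heavy chain locus had an excess of 12. With 1 library per cell type the 3 explanations cannot be told apart. The unsettled genotype of the Treg library and a difference in depth were not tested here and stay open too.

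For list-only peaks as a whole, a calling threshold is a candidate explanation, with at least 86.2% of them in the 3 lowest deciles of their own list. Signal at sites without CTCF is argued against as the source of all list-only peaks, since the motif was at least 20.1 times as frequent at list-only summits as 1 kb away. It stays open for the list-only peaks without the motif, which were 1619 of 3475 Tcon-only and 1216 of 3745 Treg-only peaks. The hypothesis that Treg identity genes gained Treg-only peaks had its predicted percentile, 98.85, under the main settings. The percentile fell below the threshold for gene bodies alone and at −log10 q of at least 5, though not with 50 kb to each side. It was also below with only motif-bearing peaks (82.9) and without Rora (95.8), Tnfrsf9 (97.1) or Nrp1 (97.1), but 99.7 with only peaks without the motif. Housekeeping genes, with 20% Treg-only peaks against 19.5% at the Treg signature, stood at 94.3 and, at −log10 q of at least 5, at 97.0. The hypothesis stays open, and the unsettled genotype of the Treg library and a difference in depth were not tested.

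Tcon-only peaks held the CTCF motif less often than Treg-only peaks, by 14.1 percentage points (95% interval 11.9 to 16.4). The intervals in this paragraph cover counting error over peaks, not a spread between libraries. A difference in rank of strength within the lists is argued against, since the gap was at least 13.5 points inside each of the 3 lowest deciles (43.5% against 57.8% in decile 1, 55.0% against 68.6% in decile 2 and 61.7% against 75.7% in decile 3), with intervals apart. Without the repeat-like cluster at the start of chromosome 9 it was 13.5 points, and outside promoters 12.7 points (10.3 to 15.1), which argues against either as the whole cause. A difference in strength on a scale common to both lists, which the scores do not give, was not tested and stays open. A difference between the libraries in immunoprecipitation or depth, one between the cell types and the unsettled genotype of the Treg library were not tested and stay open too.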
